A study of Brassica napus with 12 samples.

How the data were processed

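Poly(A)-selected, paired-end, stranded RNA-seq libraries of Brassica napus roots and leaves were prepared with a TruSeq kit, per the labels' protocols. The authors deposited 1 table per library with whole-number counts for 52962 gene identifiers, in 3 columns: either strand, forward and reverse. Per the file headers, reads that were unmapped, multimapping, outside any gene or ambiguous were counted apart from the genes, so such reads belong to no gene here. They made up 5.36% to 15.6% (unmapped), 7.73% to 9.66% (multimapping), 7.26% to 15.1% (outside genes) and 0.0777% to 0.113% (ambiguous) of each library. TopHat2 and Bowtie2 are named in the submitters' processing notes without version or role. The genome build, the annotation and the counting program are not given in the sources used here. Reads shared by near-identical A and C copies of a gene can be lost as multimapping or be assigned to the wrong copy, so a level of a single copy is uncertain to that extent.

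The reverse column held more than 99% of the stranded gene counts and was used as the sense count. The forward column, the opposite strand, held 0.355% to 0.723% of them. Gene totals ran from 14429867 to 21792206 per library. No pair of replicates agreed within sampling noise, with chi-square per degree of freedom from 5.55 to 40.6 over genes with at least 20 reads in the pair, so each library counted as a separate sample. Groups and replicate numbers came from the titles, treatments and tissue labels. The labels speak of biological replicates but do not say how many plants a replicate held, nor that roots and leaves with the same number came from the same plants.

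The deposited identifiers carry the chromosome and subgenome of each gene but no name. Of them, 2287 equalled a symbol in a RefSeq gene table of the Da-Ae assembly, 2 of these had a synonym, and none matched any of the 35 gene lists fixed before the data were examined, which could therefore not be tested. No coordinates were taken from that table, since the build of the counts is unknown. The chromosome in the identifier was the same as in the table for 93.2% of the matched genes that had a chromosome in both. In the absence of names the rule fixed beforehand allowed at most 2 identifiers that rose and 2 that fell per comparison. All 3 leaf calls are named because they were so few, and the chromosomes and segments were singled out after their values were seen.

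Si was compared with no Si within each organ by edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr, robust quasi-likelihood fits and two-sided tests, at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was derived from its F statistic. The organ by Si interaction was tested over all 12 libraries, and the overlap of calls by Fisher's exact test. As alternatives, DESeq2 1.42.0, limma-voom (limma 3.58.1), other scalings and filters, a replicate block, a planting date term in leaves, thinned counts and the removal of each library were run. In place of the fixed lists, and chosen after the data were seen, 23 gene groups were tested with camera at a preset correlation of 0.01: the A and C subgenomes, the 19 chromosomes, and genes higher in 1 organ than the other (a log2 difference of 2 or more, adjusted p under 0.01).

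Each library was also compared with the median of the other 5 of its organ, gene by gene, on log2 CPM with a prior count of 1, for genes with a mean CPM of at least 1 in both organs. Medians were taken over successive windows of 25 and blocks of 100 such genes along each chromosome. A window was kept when the root and leaf libraries of the same treatment and number were both shifted the same way by 0.4 or more, and a block when both were shifted by 0.12 or more. A gene was called off in a library below 1/30 of its highest CPM and on above 1/6 of it, where that highest CPM was at least 2. These settings were chosen after the data were seen.

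The tests were checked on simulated counts with 200 changed genes. In roots (42536 genes) edgeR recovered 68% of 2-fold and 96% of 4-fold changes, with 22 false calls, and DESeq2 73% and 97%, with 51. In leaves (41051 genes) edgeR recovered 28% and 85%, with 15 false calls, and DESeq2 51% and 93%, with 53. For both tools and in both organs, false calls were a larger share of all calls than the adjusted p threshold is set to hold. The recovery rates hold for counts with 200 changed genes and were not measured for fewer. The window test found 2 of 2 simulated lost windows, and the block test found 4 of 4 blocks raised by 0.2 on the log2 scale, with 1 other block. Intervals on counts are exact 95% binomial intervals and cover counting error only, not the spread between plants.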

Results

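Roots and leaves of Brassica napus (oilseed rape, an allotetraploid crop with an A and a C subgenome) were profiled after silicon supply. Plants of the variety Citizzen were grown in aerated nutrient solution. From the emergence of leaf 4 they received 1.7 mM Si as sodium metasilicate, or 3.4 mM NaCl as the sodium-matched control, for 1 week. The chloride added with NaCl was given to the no-Si plants only, so its effect cannot be told apart from that of Si. Each of the 4 groups (root no Si, root Si, leaf no Si, leaf Si) held 3 libraries, 12 in all. The leaf libraries were titled mature leaf and tagged aerial tissue. Gene counts per library ran from 15616881 to 19330076 in roots and from 14429867 to 21792206 in leaves. P-values for single genes weigh a difference against the spread between these libraries. Those of Fisher's exact test and camera set genes against other genes. The labels gave 12 February as the planting date of all no-Si libraries and 21 March for the Si libraries, except leaf Si replicate 3, which carried the earlier date. The harvest date was 28 March for all 12, so the later date fell 1 week before harvest, the length of the Si supply. The protocol gave 4 days of germination and 10 days in nutrient solution, with leaf 4 emerging when supply began. This growth could not take place between 21 and 28 March, which argues against the later date as the day of planting. No label states that it marks the start of supply. If it does, the planting date term in leaves repeats the supply in Si replicates 1 and 2. In roots the labelled date and the Si supply cannot be told apart.

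The question in roots was which transcripts differ after a week of Si. BnaA07g32570D, a gene on A07 for which the files pair no name, was almost absent from the Si roots. Its counts were 334, 345 and 294 in the no-Si libraries and 0, 4 and 0 in the Si libraries. The mean level fell from 19.9 ± 1.97 CPM (SD, n = 3) to 0.0732 ± 0.127 CPM (SD, n = 3), and summed counts gave a ratio of no Si to Si of 270.0 (95% interval 105.1 to 992.9, counting error only). Its fitted log2 fold change was −7.94 (SE 0.44; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00135), the only call among 42536 genes tested. The 31 tested genes within 20 places on each side of it had a median log2 fold change of −0.04 in Si roots and none of them was called.

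Other root genes did not pass by edgeR. BnaA03g22110D stood at 2.44 ± 0.772 CPM without Si and 8.26 ± 0.961 CPM with Si (SD, n = 3), and BnaC05g08120D at 20.5 ± 0.879 and 43.2 ± 8.58 CPM. Their log2 fold changes were 1.75 (SE 0.23) and 1.08 (SE 0.15), each with an edgeR Benjamini-Hochberg adjusted p of 0.103. BnaA09g08250D, with 100.1 ± 8.47 CPM without Si and 47.5 ± 5.14 CPM with Si, had a log2 fold change of −1.07 (SE 0.12) and the same adjusted p of 0.103 by edgeR after Benjamini-Hochberg adjustment. For all 3 genes every Si library lay on the same side of every no-Si library. Such separation was seen in 5618 root genes (13.2%) and 3824 leaf genes (9.32%), against 10% by chance. An unadjusted p under 0.05 was reached by 3767 root genes (1496 higher, 2271 lower with Si), where uniform p-values give 2127. DESeq2 called 448 (119 higher, 329 lower). Among them were BnaA03g22110D, BnaC05g08120D and BnaA09g08250D, with DESeq2 adjusted p of 1.00e-06, 9.23e-07 and 4.22e-11. On simulated root counts, which held added changed genes, DESeq2 made 51 false calls and edgeR 22. For each tool this was a larger share of its calls than the threshold is set to hold. The number of false calls among the 448 cannot be read from these simulated counts. The edgeR count of 1 became 36 without no-Si replicate 3, 4 without no-Si replicate 1, and 2 without no-Si replicate 2, Si replicate 1 or Si replicate 3.

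In leaves the same question gave 3 genes past the threshold among 41051 tested, all lower with Si. BnaA07g32570D was again nearly absent, with counts of 371, 274 and 253 without Si and 0, 2 and 0 with Si. It fell from 16.8 ± 3.01 to 0.0297 ± 0.0515 CPM (SD, n = 3), a ratio of 496.7 (95% interval 137.1 to 4107, counting error only), with a fitted log2 fold change of −8.72 (SE 0.48; edgeR, Benjamini-Hochberg adjusted p = 0.00228). BnaA09g10710D fell from 114.1 ± 9.66 to 37.7 ± 3.51 CPM (SD, n = 3; log2 fold change −1.60, SE 0.14). BnaA03g47140D fell from 17.2 ± 2.49 to 4.96 ± 0.228 CPM (SD, n = 3; log2 fold change −1.79, SE 0.16). Both had an adjusted p of 0.0451 (edgeR, Benjamini-Hochberg). These 2 calls ended with the replicate block (log2 fold changes −1.79 for BnaA03g47140D and −1.60 for BnaA09g10710D, adjusted p 0.612 each), and for each gene 10 of 19 alternatives, the block among them, ended the call. The block left these fold changes nearly unchanged, and it leaves fewer degrees of freedom for the test. Over all 19 the log2 fold changes ran from −1.91 to −1.71 for BnaA03g47140D and from −1.68 to −1.54 for BnaA09g10710D. The leaf genes with the smallest p among those with higher values, BnaA06g05150D (21.2 ± 0.886 to 43.9 ± 6.58 CPM; SD, n = 3) and BnaC03g67640D (14.4 ± 0.935 to 39.2 ± 13.02 CPM), did not pass, with adjusted p of 0.469 and 0.958 by edgeR after Benjamini-Hochberg adjustment.

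An unadjusted p under 0.05 was reached by 1679 leaf genes (568 higher, 1111 lower), fewer than the 2053 that uniform p-values give. DESeq2 called 43 (8 higher, 35 lower). Among them were BnaA06g05150D and BnaC03g67640D, with DESeq2 adjusted p of 5.08e-05 and 1.86e-04. On simulated leaf counts DESeq2 made 53 false calls and edgeR 15. Here too, each was a larger share of the tool's calls than the threshold is set to hold. The simulated counts held added changed genes, so the number of false calls among the 43 cannot be read from them. With planting date as a term no leaf gene was called by edgeR (855 genes with an unadjusted p under 0.05), and BnaA07g32570D then had a log2 fold change of −11.32 (SE 0.96) and an adjusted p of 0.283 (edgeR, Benjamini-Hochberg; over its leaf alternatives the adjusted p ran from 4.26e-66 to this value). That value rests on leaf Si replicate 3 alone, with 0 reads of this gene, so its size is no measured fold. With the same term the log2 fold changes of BnaA03g47140D and BnaA09g10710D were −1.86 (SE 0.28, against 0.16 without the term) and −1.68 (SE 0.24, against 0.14), each with an adjusted p of 1.00 (edgeR, Benjamini-Hochberg). The count of 3 became 7 without no-Si replicate 2, 5 without no-Si replicate 1, and 1 without no-Si replicate 3 or any of the Si replicates.

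**Figure D1:**
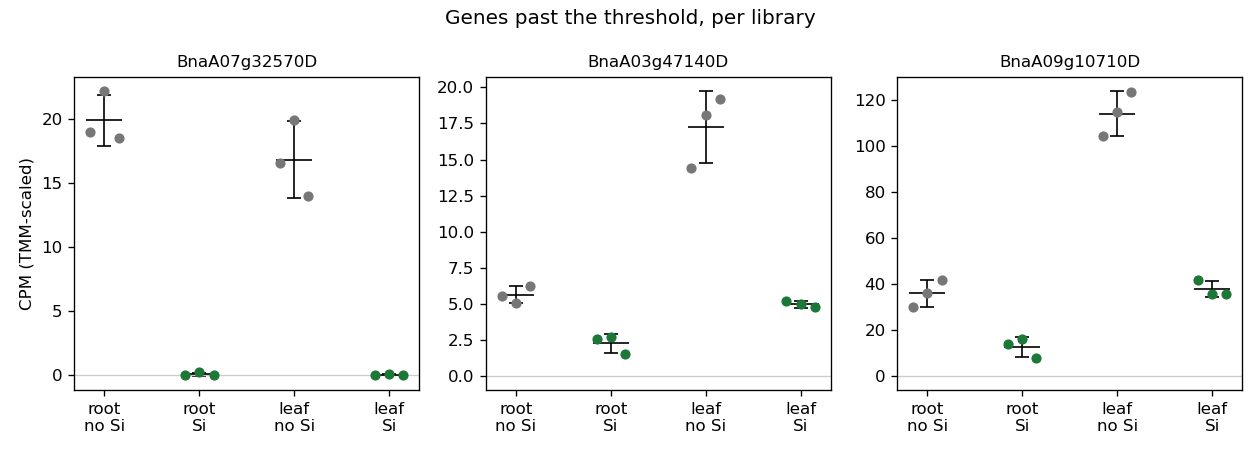
CPM (TMM-scaled, linear vertical axes) of the 3 genes past the threshold in either organ, for each of the 3 libraries per group (points; grey without Si, green with Si), with the group mean and SD as bars. BnaA07g32570D lies near 0 in all 6 Si libraries, and the leaf levels of BnaA03g47140D and BnaA09g10710D are lower with Si.

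The difference between organs was tested directly. No gene passed for the organ by Si interaction among 45222 tested with edgeR (smallest Benjamini-Hochberg adjusted p 0.958; 1823 genes with an unadjusted p under 0.05, where uniform p-values give 2261), and DESeq2 called 8. BnaA07g32570D was called in both organs. In roots BnaA03g47140D stood at 5.61 ± 0.589 CPM without Si and 2.25 ± 0.659 CPM with Si (SD, n = 3; log2 fold change −1.31, SE 0.24), and BnaA09g10710D at 35.9 ± 5.85 and 12.5 ± 4.40 CPM (log2 fold change −1.52, SE 0.26). Over all root genes their adjusted p were 0.196 and 0.207 by edgeR with Benjamini-Hochberg adjustment, and 4.07e-04 when adjusted over the 3 leaf calls alone. DESeq2 called both in roots, with adjusted p of 0.00332 for BnaA03g47140D and 1.49e-06 for BnaA09g10710D. Of 38495 genes tested in both organs, the single root call was among the 3 leaf calls (Fisher's exact test, two-sided p = 7.79e-05, with genes taken as independent). At an unadjusted p under 0.01 in each organ, roots and leaves shared 16 genes, of which 14 had the same direction (3 higher, 11 lower) against 3.21 for independent lists. DESeq2 calls shared 8 genes, all in the same direction (1 higher, 7 lower). The Fisher p, the expected 3.21 and the adjusted p over the 3 leaf calls take roots and leaves as independent, whereas libraries of the same treatment and number shared shifts of chromosome blocks.

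Gene groups that the identifiers define were compared next. C03 genes as a group were lower with Si in both organs. The median log2 fold change of 3297 C03 genes was −0.11 in roots, where 46 genes were higher and 379 lower at an unadjusted p under 0.05 (camera, Benjamini-Hochberg adjusted p = 1.98e-06), and that of 3190 C03 genes in leaves was −0.10, with 17 higher and 171 lower (adjusted p = 1.93e-04, camera with Benjamini-Hochberg adjustment). With an estimated correlation the adjusted p were 0.973 and 0.581. In roots C03 was the only group called of 23. In leaves, 2982 root-enriched genes (median log2 fold change −0.11; adjusted p = 0.0222) and 6693 leaf-enriched genes (median −0.07; adjusted p = 0.0178) were also lower with Si by camera, with an adjusted p of 0.242 for each with an estimated correlation. The A and C subgenomes did not pass in either organ, and the C share of gene counts was 51.0 ± 0.455% with Si and 51.1 ± 0.710% without in roots (SD, n = 3; exact permutation p = 0.8). The C03 difference did not pass without no-Si replicate 3, with medians of −0.06 in roots (adjusted p = 0.191 over 19 chromosomes, camera) and −0.08 in leaves (adjusted p = 0.0570, camera).

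C03 levels differed among the no-Si replicates. Relative to the other 5 libraries of the organ, the median C03 gene of no-Si replicate 3 was at log2 0.17 in roots and 0.14 in leaves. In no-Si replicate 1 the first part of the chromosome, by number of genes, stood at 0.16 and 0.15, and the second part at −0.02 in both organs. No-Si replicate 2 stood at −0.03 and −0.04, and the Si replicates between −0.07 and −0.04.

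**Figure D2:**
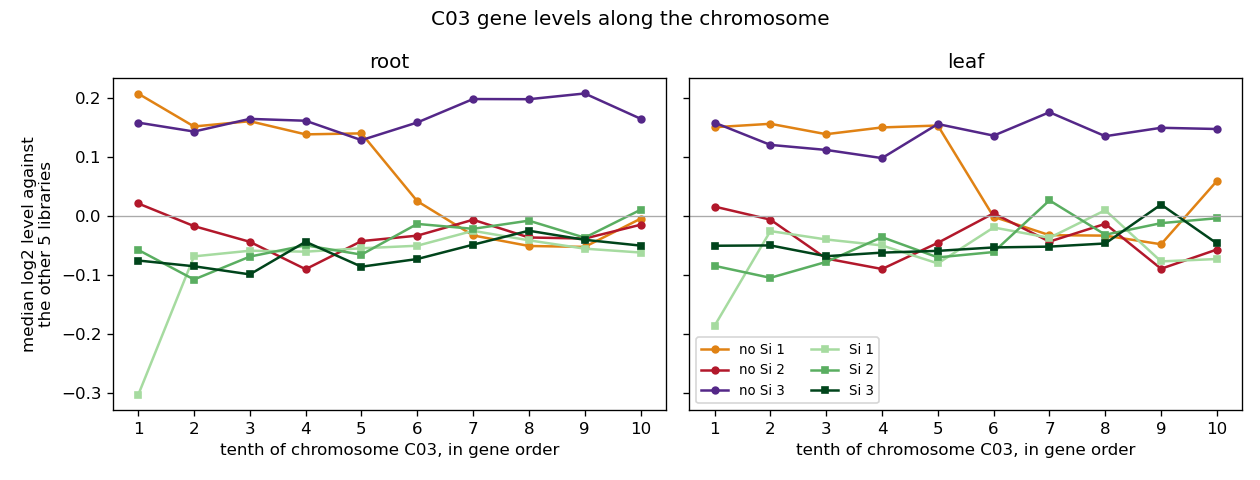
Median log2 level of C03 genes against the other 5 libraries of the organ (vertical axis) in 10 successive parts of the chromosome in gene order (horizontal axis), 1 line per treatment and replicate number, roots left and leaves right. No-Si replicate 3 is raised along the chromosome (median 0.17 in roots), no-Si replicate 1 is raised in the first part (0.16) and not in the second (−0.02), and the start of C03 is lowest in Si replicate 1.

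Other chromosome parts were shifted in 1 or more replicates, in the same direction in roots and leaves. In no-Si replicate 1, 5 blocks of A01 between BnaA01g00010D and BnaA01g13390D had a median of −0.27 in roots and −0.21 in leaves, while 6 blocks of C01 between BnaC01g00040D and BnaC01g14120D had 0.23 and 0.21. Along C07, 11 blocks between BnaC07g20290D and BnaC07g51340D had −0.19 and −0.23 in the same replicate. Blocks in the first part of C09 were lower in no-Si replicate 2 (−0.23 in roots, −0.29 in leaves) and higher in no-Si replicate 3 (0.23 and 0.18) and Si replicate 3 (0.25 and 0.23), and 1 block at the start of C09 was lower in Si replicate 2 (−0.20 and −0.16). In Si replicate 1 the start of A03 stood at 0.15 and 0.18, and the start of C03 at −0.37 and −0.28. In Si replicate 3, A04 from BnaA04g20410D to BnaA04g29730D stood at −0.17 and −0.16, and a block of C04 from BnaC04g48220D to BnaC04g50950D at 0.18 in both organs.

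The sharpest shift was in no-Si replicate 2. Over 50 expressed genes of C02, from BnaC02g42370D to BnaC02g44060D, its median level was −3.93 on the log2 scale in roots and −3.89 in leaves, and 29 of the 50 (58%) were below an eighth of the other libraries' median in both organs. The same 50 genes were shifted less in other replicates. They stood at −0.55 in roots and −0.61 in leaves of Si replicate 1, and at 0.38 and 0.65 in Si replicate 2. In the remaining replicates they stood from 0.05 to 0.19. Of the windows of 25 genes, BnaC02g42370D to BnaC02g43010D passed the threshold of 0.4 in both organs in Si replicate 1. In Si replicate 2 the window from BnaC02g43020D to BnaC02g44060D did. A window of 25 genes of A02, from BnaA02g33970D to BnaA02g34500D, stood at 0.46 and 0.51 in no-Si replicate 2. Genes of C identifiers without a chromosome, from BnaCnng01590D to BnaCnng02630D, stood at −1.59 and −1.75 there, and at 0.59 and 0.50 in Si replicate 3. On the first principal component, with 41.0% of the variance, root no-Si replicate 2 lay at −84.1 and the other root libraries from −11.3 to 43.1. In leaves, where this component held 38.4%, no-Si replicates 1 and 2 lay at opposite ends (−80.9 and 79.2) and the other libraries from −14.3 to 18.5. None of these C02, A02 or Cnn genes was called by edgeR in the Si comparison, but the median log2 fold change with Si was 0.40 in roots and 0.53 in leaves for the C02 segment (44 and 45 of 50 genes higher) and 0.38 and 0.43 for the Cnn genes (47 and 43 of 50).

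**Figure D3:**
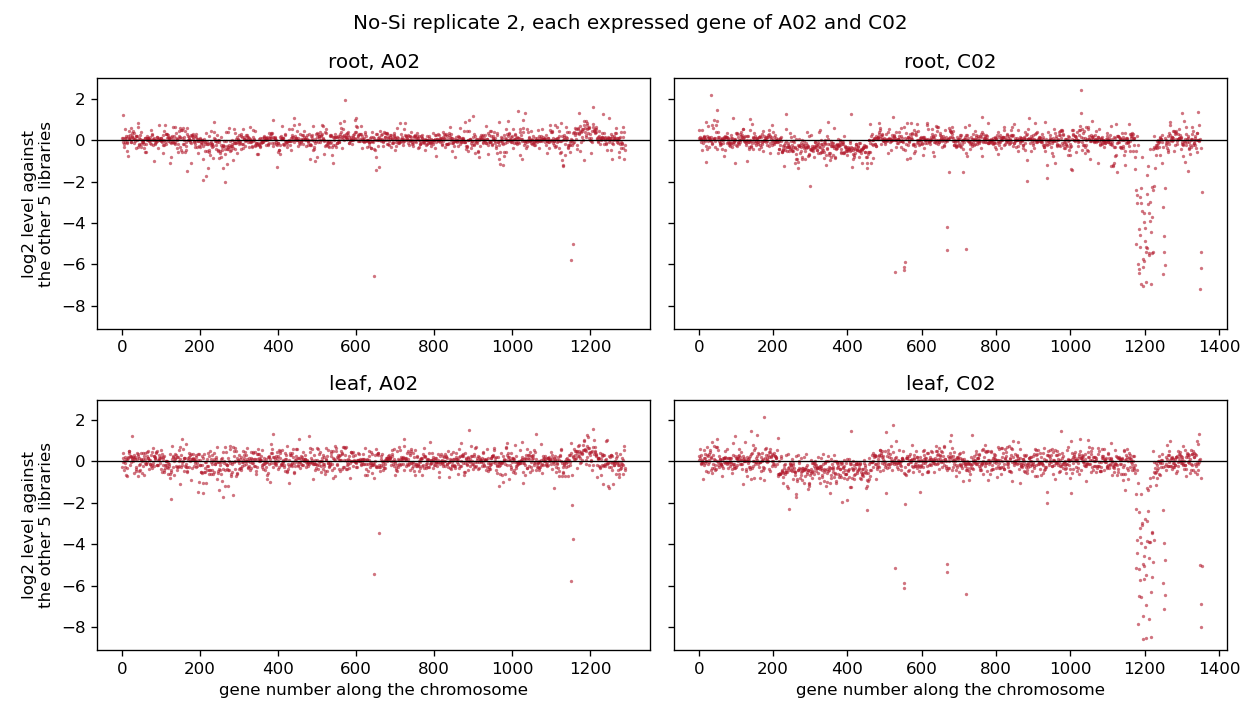
Log2 level of each expressed gene of A02 (left) and C02 (right) in no-Si replicate 2 against the median of the other 5 libraries of the organ (vertical axis), in gene order (horizontal axis), roots above and leaves below; each point is a gene and the line marks 0. A run of C02 genes lies far below 0 in both organs (median −3.93 in roots and −3.89 in leaves).

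Library composition was compared as well. Unmapped reads made up 8.62 ± 0.772% of Si root libraries and 6.85 ± 0.247% of no-Si root libraries (SD, n = 3), with no overlap (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows; Benjamini-Hochberg adjusted 1 over 20 comparisons of such measures). In leaves the unmapped share was 5.46 ± 0.145% with Si and 9.16 ± 5.60% without (SD, n = 3; exact permutation p = 0.2), with 15.6% in no-Si replicate 2. This leaf library was also the smallest, at 14429867 gene counts.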

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

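Apart from the planting date term, the tests in this part were chosen after the results were seen. Unmapped reads, which enter no gene comparison, were more frequent in every Si root library than in any no-Si root library (mean 8.62% against 6.85%). What those reads are was not analysed here.

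BnaA07g32570D separated the Si from the no-Si libraries in both organs. A longer missing or silent stretch of A07 was argued against by its tested neighbours within 20 places on each side. Their median log2 fold change was −0.041 in roots, and the lowest was −1.23 in roots and −0.48 in leaves. Neighbours with too few reads to be tested were not covered. An effect of Si supply stays open: with planting date as a term the adjusted p in leaves was 0.283, with a fitted log2 fold change of −11.32 (SE 0.96) against −8.72 (SE 0.48) without it. The term leaves Si to be judged from leaf Si replicate 3 alone, which carried the date of the no-Si libraries and had 0 reads against 253 to 371 in those, and in roots date and supply cannot be told apart. A difference between plants in carrying or expressing the gene may account for it too: in 3 of the 10 splits of the 6 combinations of treatment and number, including the real one, a gene was on in 3 and off in 3, alike in root and leaf. The gene of the real split was BnaA07g32570D itself, so only the other splits, with at most 1 such gene each, bear on this.

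C03 genes were lower with Si as a group by camera, a call lost with an estimated correlation (adjusted p 0.973 in roots and 0.581 in leaves). A camera p as small as in the real split was given by 4 of the 10 splits in roots, the real one included (8.60e-08, smallest other 3.61e-14), and by 1 in leaves (8.39e-06, smallest other 6.88e-04), too few splits for a share under 0.05. The 4 root splits were those that put no-Si replicates 1 and 3 together, and the other root splits gave a camera p of 0.0188 or more. In leaves the other splits that joined these replicates gave a camera p of 6.88e-04 to 8.51e-04, and the rest 0.0913 or more. A small camera p thus went with joining these 2 replicates, also where a Si library stood beside them. A response along the whole chromosome was argued against by its second part in no-Si replicates 1 and 2. Their root and leaf libraries, 4 of the 6 without Si, lay no more than 1 SD above the highest Si library. No-Si replicate 3 lay higher there, at 0.19 in roots and 0.15 in leaves. Root and leaf libraries of the same number shared shifts, so the 4 do not count as separate replicates. A difference in copy number of parts of C03 between replicates, which was not measured, stays open: no-Si replicate 1 had a step between the first and second part of 0.18 in roots and 0.17 in leaves, against at most 0.057 in size in the others, but without it C03 was still called (medians −0.11 in roots, adjusted p 8.15e-05, and −0.09 in leaves, adjusted p 0.00254). The call was lost without no-Si replicate 3, whose step was −0.038 in roots and −0.016 in leaves.

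Other splits of the libraries were compared with the real grouping; 10 splits are too few for a share under 0.05. In roots edgeR gave 1 gene in the real split and at most 0 in the others (1 split as large), and DESeq2 448 against at most 256 (1 split). In leaves edgeR gave 3 against at most 2 (1 split), and DESeq2 43 against at most 370 (6 splits as large); the split with 370 points to a structure of the leaf libraries. It set no-Si replicate 1 and Si replicates 2 and 3 apart from the others, with more gene counts (20335935 to 21792206 against 14429867 to 18619773), more reads outside genes (8.60% to 10.0% against 7.26% to 8.17%) and a smaller share of counts in the 10 highest genes (2.97% to 3.45% against 4.09% to 4.61%). The interaction gave 0 genes, and at most 1 in the others, so the splits say nothing about that count. Genes with an unadjusted p under 0.05 numbered 3767 in roots against at most 3526 (1 split), 1679 in leaves against at most 5091 (5 splits) and 1823 for the interaction against at most 4481 (5 splits). Gene groups numbered 1 in roots against at most 3 (5 splits) and 3 in leaves against at most 2 (1 split). Genes with an unadjusted p under 0.01 in both organs and the same direction numbered 14 against at most 28 (4 splits). The correlation of root and leaf fold changes across 38495 genes, which are not independent, was 0.342 in the real split and up to 0.379 in the others.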

How the results depend on the processing

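Alternatives fixed before the data were examined were run with others added after they were seen (either-strand counts, likelihood ratio test, quasi-likelihood without robust prior, adjusted p under 0.10, the plant block and all gene-group settings). The root count of 1 became 448 with DESeq2 and 461 with the likelihood ratio test, and ran from 1 to 36 without single libraries. The leaf count of 3 became 43 with DESeq2, 38 with the likelihood ratio test, 1 each with upper-quartile factors, limma-voom, no robust prior and an adjusted p under 0.01, and 0 with planting date as a term (855 genes with an unadjusted p under 0.05, edgeR), and ran from 1 to 7 without single libraries. The interaction count of 0 became 8 with DESeq2 and ran from 0 to 1 without single libraries (the 1 without leaf no-Si replicate 2). The shared count of 1 became 14 at an unadjusted p under 0.01 and 8 with DESeq2 calls. Gene groups numbered 0 in both organs with an estimated correlation and with fry, and ran from 0 to 3 (roots) and 0 to 4 (leaves) without single libraries, each 0 without no-Si replicate 3. The cause was not tested. Of the 11 gene values followed, none changed sign.

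Same-numbered samples of the groups compared did not deviate together throughout (correlations 0.059, 0.079 and 0.186 in roots and −0.063, −0.136 and 0.298 in leaves). Not every sample correlated best with its own number, but the Si and no-Si samples of replicate 3 did in both organs. These values do not settle what samples of the same number share. With the replicate block 1 root gene, 1 leaf gene, 1 root group and 2 leaf groups were called. The fixed gene lists had no member, so none of their alternatives was run. Thinning to the smallest library of the organ gave 3 leaf calls and 1 root call.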

Other observations

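The tests in this part were chosen after the results were seen. Genes switched between on and off among replicates were compared between organs. In roots 183 genes and in leaves 246 genes were off in at least 1 library and on in another, and 84 genes were so in both organs. Of these 84, 66 had a clear state in every library of both organs. All 66 had the same pattern in root and leaf of the same treatment and number. Genes that switched in 1 organ only were left out, so this agreement was partly set by the choice of genes. Another of the 720 ways to match root with leaf libraries gave 65, so the count mainly reflects no-Si replicate 2. Of the 66, 47 were off in no-Si replicate 2 alone (30 on C02 and 3 among C identifiers without a chromosome) and 6 were on in it alone. No-Si replicate 1 and Si replicate 2 each had 2 genes on in them alone.

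Shifts of chromosome blocks were shared by root and leaf libraries of the same treatment and number. Noise or bias of single libraries was argued against: 97 shifted blocks were found with numbers matched, and at most 24 when leaf numbers were moved to other roots in 5 ways. Another genotype of the plants behind no-Si replicate 2 is a candidate explanation for its shifts, since 17 genes were on or off in it alone outside A02, C02, C identifiers without a chromosome and the other shifted segments, against at most 1 in any other. Exchange between A and C chromosomes of the same number may also contribute, but stays open. For chromosomes 1 to 4, A and C parts moved in opposite directions (correlation −0.375 across 240 values), yet 2 of 24 ways to match A with C chromosomes were as negative, the other at −0.431.

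Of the 97 blocks, 83 were on C identifiers and 14 on A identifiers. No-Si replicates 1, 2 and 3 had 32, 17 and 27, and Si replicates 1, 2 and 3 had 5, 1 and 15, of 355 each. In the windows of 25 genes, 12 were shifted with numbers matched and at most 2 with numbers mismatched.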
